A study of Mus musculus with 11 samples.

How the data were processed

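Gene expression was measured by sequencing of polyadenylated RNA from 11 libraries of microglia-like cells from mouse brain. Per the labels the RNA was isolated with a micro column kit and turned into cDNA by reverse transcription. The authors deposited counts: whole-number reads per gene symbol, 1 table per library, with no normalization. Per the submitters' processing notes the reads were aligned with STAR, whose version is not given, to a mouse genome named both mm39 and GRCm39. The annotation, the strand setting and any filter used in counting are not given in the sources used here. No coordinates are printed. All columns were assigned to a library, so 0 were left over, and each table held the same 24411 gene symbols.

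Libraries were grouped by route (IV, ICV, ITL) and sorted population (CD45.1 µ, CD45.1 TAµ, CD45.2 µ). The 9 libraries of this complete layout were fitted in 1 additive model of route and population. It left 4 residual degrees of freedom, and 5 contrasts were taken from it. Interactions between route and population could not be tested with 1 library per combination. The CTR µ library and the ICV CD45.2 PBS library were kept out of the model. No paired analysis by animal was possible because the labels carry no animal or replicate numbers.

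Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filter for the design (minimum count 10, minimum total 15), which left 13339 in the 9 libraries and 14766 in all 11. Composition was scaled by TMM. Dispersions were estimated across genes (biological coefficient of variation 0.842), and edgeR's quasi-likelihood F test was applied with Benjamini-Hochberg adjustment at 0.05. Group levels are means of CPM with their SD over 3 libraries, counts scaled by the library total times the TMM factor. Logarithms used a prior count of 2. The SE of a fitted log2 fold change was derived from the test, as its absolute value divided by the square root of the F statistic. The direction of each tested gene was the same in all 3 blocks for 22.7% to 31.6% of genes, depending on the contrast.

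Before the data were examined, 28 gene lists were written down with 646 genes, of which 627 are in the tables. They cover microglial and macrophage states, blood and brain cell types that a sort could hold, and cell functions. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and adjusted over lists. Camera with an estimated correlation and fry's one-way test were alternatives. A separate list of X- and Y-linked genes served as a check of the animals. Some genes sit in more than 1 list, such as Pf4 among border-associated macrophage and megakaryocyte genes.

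The rule for named genes was also fixed before the data were examined. Per population contrast it took up to 12 genes each way, and per route contrast up to 6 each way, by fold change among genes past the threshold with the same direction in all 3 blocks and a mean of at least 3 log2 CPM. Where none passed, up to 5 genes each way with the smallest p were named as not having passed. Up to 4 members of each list could be named, and Ptprc, Trem2, Cx3cr1 and Apoe were followed in every comparison. Unnamed predicted genes were counted but not named. For CTR the rule took the 10 genes each way with the largest gap to the nearest of the 9 libraries, at 32 CPM or more. For PBS it took the 8 genes each way with the largest ratio, at 100 counts or more. Per-library levels of Ttr, S100a9, Slc1a3 and Xist were chosen for printing after their values were seen.

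For the single libraries, list medians were placed among 10000 random lists of the same size drawn from 20 bins of expression. A count of 0 was given the upper limit of 3 counts of the library total, and ratios of single libraries carry exact 95% intervals. Reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only. Library pairs were checked for duplicates: over 55 pairs the Spearman correlation across genes ran from 0.811 to 0.982, and no pair differed as little as sampling noise alone would allow (lowest chi-square per degree of freedom 42.8).

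The model was tested on simulated data with the dispersions and library sizes of the real tables, in which 67 genes changed by 1, 67 by 2 and 66 by 4 log2 units. For CD45.1 TAµ against CD45.1 µ it recovered 8.96%, 31.3% and 59.1% of them with 6 false calls among 72. For CD45.2 µ against CD45.1 µ it recovered 2.99%, 41.8% and 62.1% with 12 among 83, for ICV against IV 5.97%, 32.8% and 60.6% with 8 among 74, for ITL against IV 5.97%, 28.4% and 60.6% with 4 among 67, and for ITL against ICV 1.49%, 23.9% and 50.0% with 3 among 53.

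Alternatives planned before the data were examined were DESeq2's size factors within edgeR, no filter, a filter of 10 CPM in 3 libraries, DESeq2, limma-voom with quality weights, the legacy quasi-likelihood fit, no block, the 6 libraries of a contrast alone, all 11 libraries and each library left out in turn. In the fit with all 11 libraries CTR and PBS each formed a population of their own, and CTR was coded as IV. These 2 libraries therefore added no information on the contrasts. What changed there was which genes were kept (14766 tested) and how counts were scaled. For the single libraries the TMM factor and the prior count were varied. Chosen after seeing the data were leaving out Rn45s, leaving out IV CD45.2 µ and ICV CD45.1 µ, and thinning every library to the smallest total. Reads that small nucleolar RNAs share with their host genes, and that X and Y homologues share with each other, could not be told apart from the tables. Raw reads were not used here.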

Results

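Polyadenylated RNA was sequenced from microglia-like myeloid cells sorted from mouse brains after competitive transplantation of blood-forming cells. The transplants were given intravenously (IV), into the cerebral ventricles (ICV) or into the lumbar intrathecal space (ITL). The 11 libraries comprised 3 sorted populations for each of the 3 routes, named by their CD45 allele and cell type as CD45.1 µ, CD45.1 TAµ and CD45.2 µ. To these came an ICV CD45.2 library labelled PBS and a control (CTR) µ library. The labels expand neither TAµ nor PBS, and they do not say which allele marks the host. There were no replicates: each combination of route and population had 1 library.

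Total counts ran from 6090589 in ITL CD45.2 µ to 21282823 in ICV CD45.2 µ. They were 17048115, 14802989 and 12938826 for IV CD45.1 µ, IV CD45.1 TAµ and IV CD45.2 µ, and 11139686 and 11961069 for ICV CD45.1 µ and ICV CD45.1 TAµ. ITL CD45.1 µ and ITL CD45.1 TAµ had 10947623 and 9513898, the PBS library 19611137 and CTR 13066068. A count of 0 allowed a level of up to 0.151 CPM (counts scaled to a common library total) in the PBS library and up to 0.467 CPM in ITL CD45.2 µ. The 45S pre-ribosomal transcript Rn45s took between 6.98% of counts (ICV CD45.1 µ) and 25.1% (ICV CD45.1 TAµ). The fewest genes with a count were found in IV CD45.2 µ (10477) and ICV CD45.1 µ (11456), against 15492 in IV CD45.1 TAµ, so counts of changed genes were also taken without those 2 libraries. Population contrasts were blocked by route and route contrasts by population, so their p-values cover the spread between sorted populations or routes and not between animals.

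The CTR µ library was set beside the 9 libraries of the complete layout to ask how cells sorted after transplantation differed from control cells. All 30 homeostatic microglia genes were higher in CTR than the mean of the 9, with a median log2 difference of 1.29, above all 10000 random lists of like expression. Crybb1, a crystallin gene enriched in adult microglia, had 75.1 CPM in CTR and at most 30.2 CPM in the others, and the fractalkine receptor gene Cx3cr1 had 5310 CPM against 1982 to 3490 CPM. Of 26 genes of the list for graft-derived brain macrophages, 25 were lower in CTR (median log2 difference -2.13). Apoe, which encodes the main lipid carrier of the brain, had 576 CPM in CTR and 3980 to 31114 CPM in the 9 libraries, so that their mean was 32.5-fold higher. Ms4a7, a marker of brain macrophages of blood origin, had 5.74 CPM in CTR and at least 36.8 CPM in the others.

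Further genes lay outside the range of all 9 libraries. The receptor genes Gpr165 and Adora3 had 275 and 44.2 CPM in CTR and at most 47.7 and 19.5 CPM elsewhere, and the channel-like gene Tmc7 had 109 CPM against at most 33.0 CPM. The small nucleolar RNAs Snord32a, Snord34, Snord49b, Snord68, Snord89 and Snord99 were also higher in CTR, and Snord32a had 700 CPM against at most 275 CPM. Small nucleolar RNAs as a class took 0.636% of counts in CTR and 0.0449% to 0.327% in the 9 libraries. The single small nucleolar RNAs cannot be parted from this difference of the class. Below the range were the aryl hydrocarbon receptor gene Ahr (4.49 CPM against at least 32.3), the receptor kinase gene Axl (36.4 against at least 234), the chemokine receptor gene Cxcr4 (12.1 against at least 81.5) and Cyp4f18 (4.91 against at least 32.6). The proliferation marker Mki67 had 10.9 CPM in CTR and 75.5 to 153 CPM in the 9 libraries, with 33 of 39 cell cycle genes lower in CTR (median log2 difference -1.47). Sorbs3 and Atrnl1 were at 2.58 and 3.83 CPM in CTR against at least 16.8 and 22.7 CPM. Xist, the RNA of the inactive X chromosome, had 0 counts in CTR, which allows up to 0.25 CPM, and at least 11.5 CPM in each of the others. Y-linked transcripts summed to 339 CPM in CTR, so the gap in Xist cannot be parted from the sex of the cells.

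Lists for monocytes (median log2 difference -1.33), MHC class II presentation (-0.98), border-associated macrophages (-0.72), lipid and cholesterol handling (-0.60), interferon response (-0.54) and disease-associated microglia (-0.48) were lower in CTR than the mean of the 9, each at the 0.01 percentile of the random lists or under. Of these 6 only the disease-associated list had its lowest mean in CTR (6.51 log2 CPM, against at least 6.86). IV CD45.2 µ was lower than CTR for monocytes (-0.06 against 2.69), MHC class II presentation (5.16 against 5.32), border-associated macrophages (3.43 against 3.72), lipid handling (3.38 against 3.53) and interferon response (2.54 against 3.37). ICV CD45.1 µ was also lower for monocytes (2.34), as was ITL CD45.2 µ for interferon response (3.23). The immediate-early list was 0.38 above the mean of the 9, but its level in CTR (9.33 log2 CPM) was inside their range, with IV CD45.1 µ at 9.34, IV CD45.1 TAµ at 9.87 and ICV CD45.2 µ at 9.39. The neutrophil list had no single direction: its median was at -0.74 against CD45.1 µ, -0.024 against CD45.1 TAµ and 1.97 against CD45.2 µ, with a list mean of 5.29 log2 CPM in CTR and -1.36 log2 CPM in IV CD45.2 µ. Markers of other brain cells differed as well: the astrocyte list was at -0.72 and the oligodendrocyte list at -0.50 against the mean of the 9, but at 0.26 and 0.53 against CD45.1 µ, -0.51 and -1.01 against CD45.1 TAµ, and -1.58 and -1.51 against CD45.2 µ. Microglial receptor genes did not all differ: Ptprc, the CD45 gene, had 535 CPM and Trem2 449 CPM in CTR, inside the range of the 9 libraries. In all, 245 of 14766 genes lay more than 1 log2 unit outside that range, 105 above and 140 below. With 1 CTR library no test was possible, and its difference cannot be parted from animal, sex, genotype or handling, none of which its labels give.

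**Figure D1:**
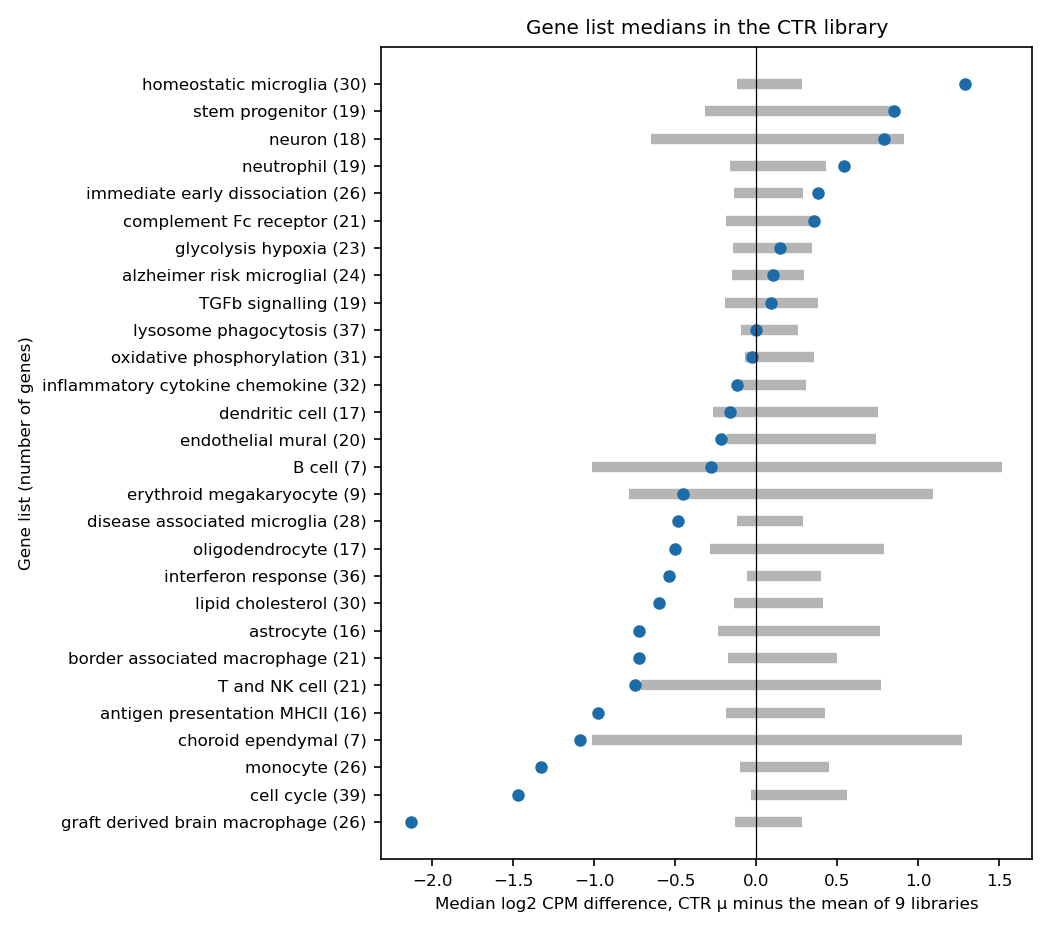
Median log2 CPM difference (points) of each of the 28 gene lists between the CTR µ library and the mean of the 9 transplant libraries, beside the central 95% of medians of random lists (grey bars) of like size and expression. The homeostatic microglia list lies at 1.29 and the graft-derived macrophage list at -2.13.

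CD45.1 TAµ was compared with CD45.1 µ to ask how these populations of the same allele differed. Sall1, a transcription factor that maintains microglial identity, fell by 4.83 ± 0.49 (SE) on the log2 scale, from 176 ± 145 CPM in CD45.1 µ to 5.98 ± 3.42 CPM in CD45.1 TAµ (SD, n = 3; adjusted p = 0.000199). Its relative Sall3 fell by 4.96 ± 0.76 to 1.29 ± 0.671 CPM from 41.9 ± 36.0 CPM (adjusted p = 0.00826), and Nav3, a cytoskeletal gene of the homeostatic microglia list, fell by 3.25 ± 0.52 (adjusted p = 0.0188). Also lower were Adamts1, a secreted protease (log2 fold change -4.26 ± 0.76, adjusted p = 0.0404), Sgce, a sarcoglycan (-4.37 ± 0.81, adjusted p = 0.0428), and St3gal5, the synthase of ganglioside GM3 (-2.48 ± 0.40, adjusted p = 0.0188). Xist fell by 4.01 ± 0.54 (adjusted p = 0.00729), from 2433 ± 2876 CPM to 185 ± 264 CPM. The RNAs that rose were Snord32a (3.22 ± 0.47, adjusted p = 0.00826), Snord104 (3.22 ± 0.52, adjusted p = 0.0188) and Rmrp, the RNA of a mitochondrial and nucleolar endonuclease (1.97 ± 0.34, adjusted p = 0.0397). Small nucleolar RNAs as a class took more of the counts in CD45.1 TAµ (0.156%, 0.327% and 0.205% by IV, ICV and ITL) than in CD45.1 µ (0.0803%, 0.0449% and 0.112%). In the fit over routes Snord32a rose 9.35-fold and Snord104 9.34-fold. How far these rises go with the shift of the class, and the cause of that shift, were not tested.

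These were all 10 genes of 13339 that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 higher and 7 lower, each with the same direction in 3 of 3 routes. At an unadjusted p under 0.05 there were 715 genes, where chance gives 667. Ptprc (log2 fold change 0.33 ± 0.23, adjusted p = 0.874), Trem2 (0.20 ± 0.32, 0.939), Cx3cr1 (-0.039 ± 0.20, 0.986) and Apoe (0.15 ± 0.39, 0.968) did not pass. Xist differed between the CD45.1 µ libraries themselves: 294 CPM by the IV route, 1304 CPM by ITL and 5702 CPM by ICV. By each route Xist was lower and the sum of Y-linked transcripts was higher in CD45.1 TAµ than in CD45.1 µ. The contrast therefore cannot part the population from the sex of the cells, for single genes or for lists. Without 1 library the count went from 10 to 0 (IV CD45.1 TAµ), 1 (ITL CD45.1 µ), 1 (ICV CD45.1 µ), 5 (ITL CD45.1 TAµ), 10 (ITL CD45.2 µ), 12 (ICV CD45.1 TAµ), 16 (ICV CD45.2 µ), 18 (IV CD45.1 µ) or 24 (IV CD45.2 µ). The sign of all 10 genes held without any 1 library, but sizes moved. Without ICV CD45.1 TAµ the log2 fold change was -6.26 for Adamts1, -5.03 for Xist, -3.98 for Nav3 and 2.63 for Snord32a. Without IV CD45.1 TAµ it was -3.23 for Adamts1, without IV CD45.1 µ -5.58 for Sall3, and without ICV CD45.1 µ 2.56 for Snord32a and 2.39 for Snord104. The number of genes called was 217 with DESeq2, 23 with no filter, 24 with all 11 libraries, 2 with a stricter filter, 3 with the legacy quasi-likelihood fit and 2 with no block.

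Of the 30 homeostatic microglia genes, 3 fell in CD45.1 TAµ (Sall1, Sall3 and Nav3), 8 fell when adjusted over the list alone, and 25 had a negative fold change (median log2 fold change -0.31, mean -1.12). The list passed camera (adjusted p = 2.63e-10) but not with an estimated correlation (adjusted p = 0.632). All 16 MHC class II presentation genes were fitted higher, with H2-Eb1 at 1.71 ± 0.33 (adjusted p = 0.0725), H2-Aa at 1.46 ± 0.30 (0.1000) and Cd74 at 1.22 ± 0.29 (0.275), none of which passed. Of that list, 0 rose over all genes and 4 rose when adjusted over the list alone (camera adjusted p = 0.00379; adjusted p = 0.632 with an estimated correlation). T and NK cell genes were fitted higher for 14 of 15 members (camera adjusted p = 4.66e-07; adjusted p = 0.632 with an estimated correlation). None of these passed singly; Gzmb, the gene of granzyme B, had 0 counts in each CD45.1 µ library and 3.55, 4.39 and 3.92 CPM in CD45.1 TAµ by IV, ICV and ITL.

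Markers of brain cells also moved with CD45.1 TAµ: camera gave an adjusted p of 0.00502 for oligodendrocytes and 0.00379 for endothelial and mural cells, both higher (adjusted p = 0.947 for each with an estimated correlation). Each had 0 members that passed over all genes and 2 that rose when adjusted over the list alone. The list of 24 microglial genes at Alzheimer's disease risk loci was lower, with 16 members negative and 8 positive (median log2 fold change -0.26, camera adjusted p = 0.0109, with 0 called over all genes or over the list alone). That call was lost with an estimated correlation (adjusted p = 0.632). The mean of the risk gene list was not lower by ITL (7.40 log2 CPM in CD45.1 TAµ against 7.37 in CD45.1 µ). Without IV CD45.2 µ and ICV CD45.1 µ the homeostatic (adjusted p = 9.90e-10) and T and NK cell (0.000298) lists still passed camera, while the MHC class II (0.0889), oligodendrocyte (0.516), endothelial (0.139) and risk gene (0.0741) lists did not.

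CD45.2 µ was compared with CD45.1 µ to ask how µ cells of different CD45 alleles differed. The aspartic protease gene Ctse fell by 3.82 ± 0.60 (SE) on the log2 scale, from 168 ± 83.3 CPM in CD45.1 µ to 10.9 ± 12.9 CPM in CD45.2 µ (SD, n = 3; adjusted p = 0.0423). The other genes that fell lie on the Y chromosome and are expressed in male cells. Ddx3y fell by 3.42 ± 0.50 (adjusted p = 0.0358) to 10.6 ± 16.2 CPM from 110 ± 117 CPM, Uty fell by 3.73 ± 0.62 (adjusted p = 0.0423), and Kdm5d went from 25.9 ± 8.76 CPM to 0.119 ± 0.207 CPM (adjusted p = 0.0444). Xist, their counterpart in female cells, had 3704, 6967 and 5116 CPM in CD45.2 µ by IV, ICV and ITL. By each route Xist was higher and Y-linked transcripts were lower in CD45.2 µ than in CD45.1 µ. The contrast therefore cannot part the allele from the sex of the cells, for single genes or for lists. Ctse had 26.2 CPM in the PBS library and 2.58 CPM in CTR.

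Only these 4 of 13339 genes passed edgeR's test with Benjamini-Hochberg adjustment, all lower in CD45.2 µ in 3 of 3 routes, and 1172 had an unadjusted p under 0.05. Apoe was at a log2 fold change of -1.32 ± 0.42 and did not pass (adjusted p = 0.485). With 1 library left out, that of Apoe ran from -2.05 to -0.78. Ptprc (-0.09 ± 0.23, adjusted p = 0.917), Trem2 (-0.10 ± 0.32, 0.939) and Cx3cr1 (0.25 ± 0.20, 0.717) did not pass either. Without 1 library the count was 0 (IV CD45.1 µ, ITL CD45.1 µ or ITL CD45.2 µ), 1 (IV CD45.1 TAµ, ICV CD45.1 µ or ICV CD45.1 TAµ), 3 (IV CD45.2 µ or ITL CD45.1 TAµ) or 29 (ICV CD45.2 µ). All 4 stayed lower without any 1 library, but sizes moved. Without ICV CD45.2 µ the log2 fold change was -5.98 for Ctse and -11.57 for Kdm5d, beside -6.97 for Kdm5d with all 9 libraries. Without IV CD45.2 µ it was -3.05 for Ctse, -6.09 for Kdm5d, -6.13 for Uty and -5.65 for Ddx3y, and without ICV CD45.1 µ -4.84 for Ctse. DESeq2 gave 277 genes, and 0 were called by limma-voom, the legacy quasi-likelihood fit, the stricter filter, the fit with no block or the fit to the 6 libraries alone.

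**Figure D2:**
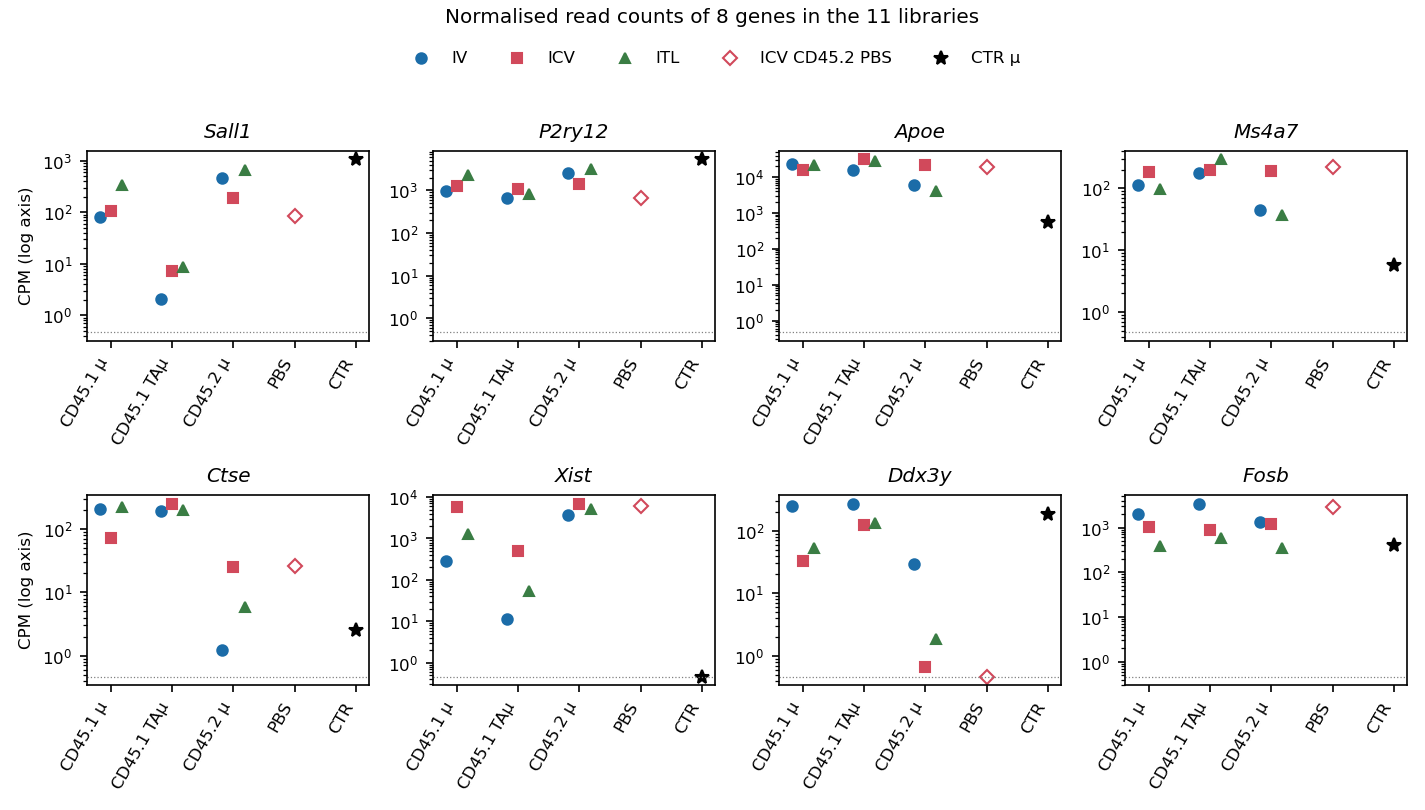
Levels in CPM, on log axes, of Sall1, P2ry12, Apoe, Ms4a7, Ctse, Xist, Ddx3y and Fosb, with 1 point for each of the 11 libraries and values under the dotted limit of 0.467 CPM drawn on it. Ctse was lower in each CD45.2 µ library than in the CD45.1 µ library of the same route, and Sall1 was lower in each CD45.1 TAµ library than in the CD45.1 µ library of the same route.

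Macrophage lists were lower in CD45.2 µ in the fit over routes, but not all of them by every route. By ICV the graft-derived list mean was 7.75 log2 CPM in CD45.2 µ and 7.59 in CD45.1 µ. The interferon response list, also lower in the fit, had 4.55 and 4.06 log2 CPM in these ICV libraries. Of 21 border-associated macrophage genes, 18 had a negative fold change (median -0.90), among them the mannose receptor gene Mrc1 (-1.32 ± 0.29, adjusted p = 0.389), Siglec1 (-1.45 ± 0.34, 0.389) and the chemokine gene Pf4 (-1.76 ± 0.46, 0.457). Of that list, 0 fell over all genes and 6 fell when adjusted over the list alone (camera adjusted p = 0.000151; adjusted p = 0.647 with an estimated correlation). Of 26 graft-derived macrophage genes, 23 were negative (median -0.70), 0 fell over all genes and 9 fell when adjusted over the list alone (camera adjusted p = 3.67e-06; adjusted p = 0.898 with an estimated correlation). The interferon response list was lower, with 24 members negative and 12 positive (median -0.50, camera adjusted p = 0.000676; adjusted p = 0.911 with an estimated correlation) with 0 called over all genes or over the list alone. The homeostatic microglia list was higher, with 24 of 30 members positive (median 0.36, camera adjusted p = 0.0133; adjusted p = 0.911 with an estimated correlation), with 0 called over all genes and 5 that rose when adjusted over the list alone.

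Lists of other cells moved with CD45.2 µ as well. Endothelial and mural (camera adjusted p = 1.16e-06), astrocyte (4.96e-05), oligodendrocyte (0.000526) and erythroid and megakaryocyte (0.0126) lists were higher and the neutrophil list lower (0.00996). With an estimated correlation their adjusted p values were 0.898, 0.898, 0.898, 0.647 and 0.911. No member passed over all genes. Adjusted over the list alone, 9 endothelial, 5 astrocyte, 0 oligodendrocyte and 3 erythroid genes rose, 1 erythroid list gene (Pf4, also a macrophage gene) fell and 0 neutrophil genes changed. The astrocyte glutamate transporter gene Slc1a3 had 179 and 192 CPM in CD45.2 µ by IV and ITL against 26.2 and 71.3 CPM in CD45.1 µ. The neutrophil gene S100a9 had 0 counts in IV CD45.2 µ and 3828 CPM in IV CD45.1 µ, but 879 CPM in ICV CD45.2 µ against 304 CPM in ICV CD45.1 µ, and 1017 against 1176 CPM by ITL. Without IV CD45.2 µ and ICV CD45.1 µ the graft-derived (adjusted p = 0.000215), border-associated (0.000174) and erythroid (0.0300) lists still passed camera. In that fit only ITL kept both µ populations, so it does not show that a difference holds across routes. The homeostatic (0.999) and neutrophil (0.999) lists turned direction, and the astrocyte (0.632), oligodendrocyte (0.647), endothelial (0.231) and interferon (0.0745) lists no longer passed.

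ITL was compared with IV to ask whether the route of transplantation changed the cells. Several immediate-early genes, which respond within minutes to stimulation or tissue dissociation, fell in ITL. Fosb fell by 2.33 ± 0.28 (SE) on the log2 scale, from 2276 ± 1064 CPM in IV to 445 ± 133 CPM in ITL (SD, n = 3; adjusted p = 0.00171), and Fos fell by 1.47 ± 0.23 (adjusted p = 0.00838). The transcription factor gene Klf2 fell by 1.77 ± 0.22, from 769 ± 63.6 CPM to 227 ± 19.5 CPM (adjusted p = 0.00171). The circadian gene Per1 fell by 1.77 ± 0.24 (adjusted p = 0.00428), the kinase gene Pim3 by 1.78 ± 0.33 (0.0289), and the transcription factor genes Maff by 2.04 ± 0.40 (0.0410) and Zbtb10 by 2.0 ± 0.33 (0.0115). The inflammatory regulators Tnfaip3 (-1.72 ± 0.23, adjusted p = 0.00428) and Nlrp3 (-1.38 ± 0.24, 0.0148) fell, and Snord32a rose (2.89 ± 0.46, 0.00941). Small nucleolar RNAs as a class took 0.112%, 0.205% and 0.179% of counts in ITL CD45.1 µ, CD45.1 TAµ and CD45.2 µ, against 0.0803%, 0.156% and 0.140% in IV. Snord32a rose 7.43-fold in the fit, a larger step than the class made in any population. The cause of either rise was not tested.

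In all, 29 of 13339 genes passed edgeR's test with Benjamini-Hochberg adjustment, 1 higher and 28 lower, each with the same direction in 3 of 3 populations. The 28 that fell had log2 fold changes from -2.33 to -1.18, and 714 genes had an unadjusted p under 0.05. Ptprc (0.38 ± 0.23, adjusted p = 0.915), Trem2 (0.23 ± 0.32, 0.933), Cx3cr1 (0.51 ± 0.20, 0.807) and Apoe (0.11 ± 0.39, 0.973) did not pass. Without 1 library the count went from 29 to 0 (IV CD45.1 TAµ or ITL CD45.1 µ), 1 (ITL CD45.1 TAµ), 4 (IV CD45.1 µ), 15 (ITL CD45.2 µ), 24 (ICV CD45.1 µ), 25 (ICV CD45.2 µ), 30 (ICV CD45.1 TAµ) or 35 (IV CD45.2 µ). It was 49 without IV CD45.2 µ and ICV CD45.1 µ together, 150 with DESeq2 and 66 with limma-voom. It was 12, 10 and 13 with the stricter filter, the legacy fit and no block. Xist had 1304, 54.6 and 5116 CPM in ITL CD45.1 µ, CD45.1 TAµ and CD45.2 µ, against 294, 11.5 and 3704 CPM in IV. Y-linked transcripts summed to 162, 314 and 3.43 CPM in these ITL libraries against 348, 458 and 42.2 CPM in IV. The contrast therefore cannot part the route from the sex of the cells, for single genes or for lists.

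**Figure D3:**
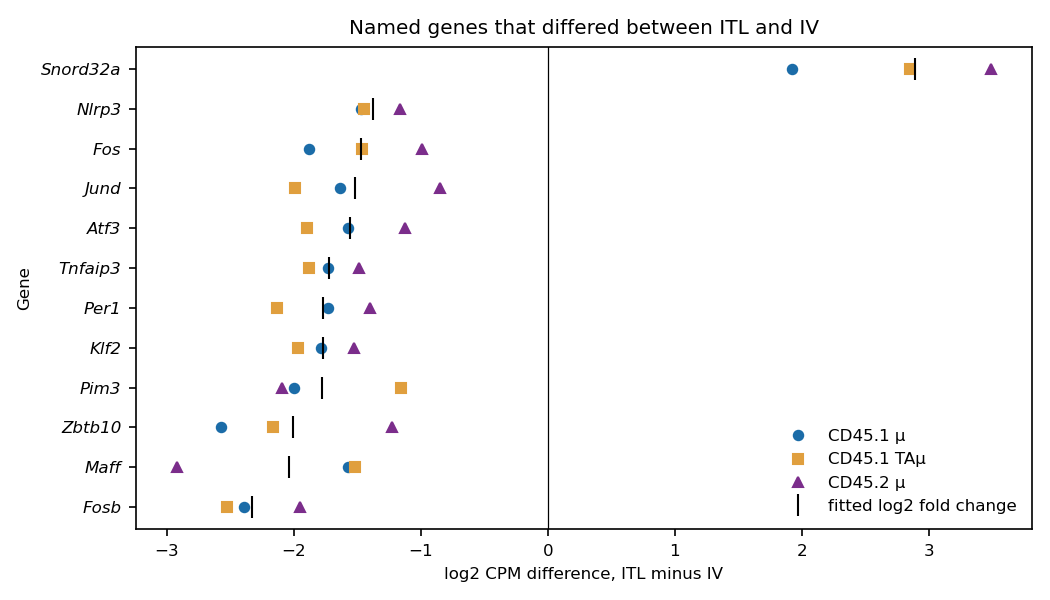
Difference in log2 CPM between ITL and IV in each of the 3 populations (1 point each) for the genes named by the rule or as list members that passed the test, with the fitted log2 fold change as a vertical mark. All 3 points lie below 0 for each gene except Snord32a, whose points lie above 0.

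Of the 26 immediate-early genes, 9 fell over all genes, 18 fell when adjusted over the list alone and 23 had a negative fold change (median -0.85). The list passed camera (adjusted p = 6.27e-15) but not with an estimated correlation (adjusted p = 0.740). Its mean was lower in ITL by every population pair: the log2 differences were -0.99 in CD45.1 µ, -1.23 in CD45.1 TAµ and -0.34 in CD45.2 µ. The CTR library stood at a list mean of 9.33 log2 CPM, beside 8.35 to 8.88 in ITL and 9.21 to 9.87 in IV. Of 31 inflammatory cytokine and chemokine genes, 2 fell over all genes (Tnfaip3 and Nlrp3); adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.0204). Interferon response genes were negative for 30 of 36 members (0.0204), and the stem and progenitor list was lower, with 12 of 17 members negative (0.0204), each with 0 called over all genes or over the list alone. These 3 lists had an adjusted p of 0.740 with an estimated correlation. In the CD45.2 µ pair their means went the other way. ITL against IV stood at 5.561 against 5.445 log2 CPM for cytokines, 3.23 against 2.54 for interferon response and 1.36 against 0.98 for stem and progenitor genes.

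Higher in ITL by camera were the lists for monocytes (adjusted p = 0.00107), oligodendrocytes (0.00107), homeostatic microglia (0.0249) and complement and Fc receptors (0.0249), each with an adjusted p of 0.740 with an estimated correlation. Over all genes 0 members of the 4 lists rose. Adjusted over the list alone, 2 monocyte, 3 oligodendrocyte, 4 homeostatic and 0 complement genes rose. Klf2, counted here as a monocyte gene, fell against the direction of its list. The monocyte list did not pass without IV CD45.2 µ and ICV CD45.1 µ (adjusted p = 0.950, with the direction turned), where its mean in IV CD45.2 µ was -0.06 log2 CPM against 5.80 in ITL CD45.2 µ. With no block the homeostatic (0.122) and stem and progenitor (0.0797) lists did not pass.

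ICV was compared with IV for the same question. No gene passed edgeR's test: 0 of 13339 had an adjusted p under 0.05, 1230 had an unadjusted p under 0.05, DESeq2 called 147 and limma-voom 0. The adhesion molecule gene Vcam1 had 583 ± 64.7 CPM in ICV and 184 ± 94.4 CPM in IV (SD, n = 3; log2 fold change 1.86 ± 0.32, adjusted p = 0.0993). Also short of the threshold were Snord104 (3.13 ± 0.51, adjusted p = 0.0757), Xist (3.43 ± 0.56, 0.0757), the secreted phospholipase gene Enpp2 (5.12 ± 0.98, 0.135) and Abcb9 (5.65 ± 1.17, 0.135), all fitted higher in ICV. With 1 library left out the log2 fold change ran from 2.74 to 4.44 for Xist, 3.21 to 6.28 for Enpp2 and 4.51 to 8.92 for Abcb9. Ddx3y (-2.41 ± 0.44, adjusted p = 0.122), Egr1 (-1.63 ± 0.30, 0.135), Klf2 (-1.08 ± 0.21, 0.135) and Sqstm1 (-1.15 ± 0.23, 0.135) were fitted lower. Xist and Ddx3y mark the sex of the cells. In each population Xist was higher and the sum of Y-linked transcripts was lower in ICV than in IV. The contrast therefore cannot part the route from the sex of the cells. Ptprc (0.30 ± 0.23, adjusted p = 0.700), Trem2 (0.02 ± 0.32, 0.989), Cx3cr1 (0.50 ± 0.20, 0.491) and Apoe (0.85 ± 0.40, 0.542) did not pass either. The log2 fold change of Apoe ran from 0.0052 to 1.41 with 1 library left out. The count was 28 without IV CD45.2 µ, 5 without ITL CD45.2 µ or ICV CD45.2 µ, 2 without IV CD45.1 µ and 1 without ICV CD45.1 µ or ICV CD45.1 TAµ, and stayed at 0 without any other single library. It was 8 with no filter, 6 with all 11 libraries and 1 with the 6 libraries alone.

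By list, border-associated macrophage markers were higher in ICV (camera adjusted p = 0.00131; adjusted p = 0.705 with an estimated correlation), with 18 of 21 positive, a median of 0.71 and 6 that rose when adjusted over the list alone. Stab1, a scavenger receptor gene (0.68 ± 0.20, adjusted p = 0.343), and Mrc1 (0.91 ± 0.29, 0.398) were among those not passing over all genes. Graft-derived macrophage (camera adjusted p = 0.0487, 1 over the list alone), oligodendrocyte (0.00272, 3) and choroid plexus and ependymal lists (0.00499, 3 of 5) were also higher. With an estimated correlation their adjusted p values were 0.852, 0.705 and 0.705. The choroid plexus gene Ttr had 774 CPM in ICV CD45.1 µ, 48.4 CPM in ICV CD45.1 TAµ, 3.68 CPM in ICV CD45.2 µ and 4.62 CPM in IV CD45.2 µ. The immediate-early list was lower, with 21 of 26 members negative (camera adjusted p = 4.66e-05, 12 fell when adjusted over the list alone), as was the cell cycle list with 28 of 39 negative (0.0253, 0 over the list alone). Both had an adjusted p of 0.705 with an estimated correlation, and of these 6 lists 0 members passed over all genes. Without IV CD45.2 µ and ICV CD45.1 µ the graft-derived list did not pass (adjusted p = 0.0963) and the choroid list had too few tested members, and with no block the graft-derived list was also lost (0.149). Some list means turned in a population. In CD45.2 µ, ICV was above IV for immediate-early (9.39 against 9.21 log2 CPM) and cell cycle genes (2.89 against 2.06). In CD45.1 µ it was below IV for the graft-derived list (7.59 against 7.86).

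ITL was compared with ICV to set the central routes side by side. No gene passed edgeR's test: 0 of 13339 had an adjusted p under 0.05, 506 had an unadjusted p under 0.05, DESeq2 called 30 and limma-voom 0. Adgre4, a myeloid adhesion receptor gene, had 77.6 ± 55.0 CPM in ITL and 4.90 ± 5.06 CPM in ICV (SD, n = 3; log2 fold change 4.06 ± 0.71, adjusted p = 0.119). Vcam1 had 177 ± 124 CPM in ITL against 583 ± 64.7 CPM in ICV (-1.98 ± 0.33, adjusted p = 0.119). Ace (2.90 ± 0.69), the kinase gene Fgr (2.5 ± 0.60), Gngt2 (1.85 ± 0.45) and Lrrc3 (1.29 ± 0.31) were fitted higher in ITL, each with an adjusted p of 0.681. With 1 library left out the log2 fold change ran from 3.14 to 4.76 for Adgre4 and 1.99 to 3.75 for Ace. It ran from 1.94 to 3.40 for Fgr and 1.39 to 2.55 for Gngt2. Fosb (-1.31 ± 0.27), the chaperone gene Dnajb1 (-1.60 ± 0.34), the endocytic adaptor gene Dab2 (-1.19 ± 0.27) and Stab1 (-0.87 ± 0.20) were fitted lower at the same adjusted p. Ptprc (0.08 ± 0.23, adjusted p = 0.998), Trem2 (0.21 ± 0.32, 0.998), Cx3cr1 (0.01 ± 0.20, 0.999) and Apoe (-0.74 ± 0.41, 0.998) did not pass. The count was 3 without ICV CD45.1 TAµ, 1 without IV CD45.2 µ or ICV CD45.2 µ, 0 without any other single library, and 2 without IV CD45.2 µ and ICV CD45.1 µ together. It was 2 with no filter or all 11 libraries and 1 with the 6 libraries alone. In each population Xist was lower and the sum of Y-linked transcripts was higher in ITL than in ICV. These routes therefore cannot be parted from the sex of the cells either.

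Monocyte genes were fitted higher in ITL than ICV for 25 of 26 members (median 1.22, camera adjusted p = 0.000131; adjusted p = 0.851 with an estimated correlation), 7 of which rose and 1 of which, Klf2, fell when adjusted over the list alone. Cell cycle (camera adjusted p = 0.00315, 0 over the list alone) and homeostatic microglia lists (0.0310, 2 over the list alone) were also higher, with an adjusted p of 0.851 and 0.911 with an estimated correlation. Immediate-early (0.000125, 7 over the list alone), interferon response (0.00315, 0) and border-associated macrophage lists (0.0213, 3) were lower, each with an adjusted p of 0.851 with an estimated correlation. Of these 6 lists 0 members passed over all genes. The homeostatic list did not pass without IV CD45.2 µ and ICV CD45.1 µ (adjusted p = 0.251) or with no block (0.254), and the border-associated list did not pass with no block (0.0842). Some list means turned in a population. In CD45.1 TAµ, ITL was below ICV for homeostatic genes (7.415 against 7.644 log2 CPM) and above it for interferon response (4.53 against 4.32). In CD45.1 µ it was above ICV for border-associated macrophages (5.21 against 5.03).

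The ICV CD45.2 library labelled PBS was set beside ICV CD45.2 µ, with 1 library each and so no test. Among the genes with the largest ratios in favour of PBS, the myeloperoxidase gene Mpo had 1490 counts (75.1 CPM) against 0 counts, which allows up to 0.153 CPM, and the neutrophil elastase gene Elane had 31.7 against 0.409 CPM. Prtn3 had 18.7 against 0.358 CPM, the eosinophil granule gene Prg2 11.5 against 0.256 CPM and Epx 8.77 CPM against 0 counts, while Cldn1 had 5.60 CPM against 0 counts. The progenitor transcription factor gene Myb had 6.91 against 0.102 CPM, and 13 of 19 stem and progenitor genes and 37 of 39 cell cycle genes were higher (median log2 difference 0.82 for the latter). Of the monocyte list, 22 of 26 genes were higher in PBS (median 0.60), while of the neutrophil list 6 were higher and 13 lower (median -0.14). All 30 homeostatic microglia genes were lower in PBS (median -0.69), and Cx3cr1 had 1821 against 3392 CPM.

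Markers of other brain cells were lower in PBS, with 16 of 16 astrocyte, 15 of 17 oligodendrocyte and 18 of 20 endothelial and mural genes below ICV CD45.2 µ. The myelin genes Ermn and Mal had 0 counts and 0.101 CPM in PBS against 9.62 and 11.6 CPM. The matrix and vessel genes Bgn and Igfbp5 had 0.202 and 0.504 CPM against 18.1 and 31.7 CPM. Apoe (log2 difference -0.15), Ptprc (0.22) and Trem2 (-0.42) differed by less than 1 log2 unit. Beyond a factor of 2 there were 784 genes, 388 higher and 396 lower in PBS; without the composition factor there were 838, 520 higher and 318 lower. Intervals and limits for these libraries cover counting error only.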

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

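The comparisons of list means between routes in this part were chosen after the values were seen. Each entry is a list whose mean log2 CPM moved one way by at least 1 log2 unit in 1 route and the other way by at least 1 log2 unit in another, with 1 library on each side, and the difference was not tested in any of them.

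For neutrophil genes, CD45.1 TAµ minus CD45.1 µ was 1.04 by ICV, -0.93 by IV and -1.05 by ITL, a difference of 2.08 between ICV and ITL that was not tested. For the same genes, CD45.2 µ minus CD45.1 µ was -8.78 by IV, 2.55 by ICV and -0.051 by ITL, a difference of 11.3 between ICV and IV. For monocyte genes it was -4.23 by IV, 2.12 by ICV and 1.03 by ITL, a difference of 6.36. Dendritic cell genes were at -1.46, 1.5 and 0.79 by IV, ICV and ITL, a difference of 2.96. Choroid plexus and ependymal genes were at 0.60, -3.54 and 2.16, a difference of 5.70 between ITL and ICV. Neutrophil genes averaged -1.36 log2 CPM in IV CD45.2 µ and 7.42 in IV CD45.1 µ, and choroid plexus genes 3.12 in ICV CD45.1 µ and -0.42 in ICV CD45.2 µ. No explanation was tested for these list differences.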

How the results depend on the processing

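Leaving out Rn45s, leaving out IV CD45.2 µ and ICV CD45.1 µ together, and thinning to the smallest total were chosen after the data were seen; the other alternatives were planned. Of the values for single named genes and single-library list medians under the alternatives, 1004 kept their direction and side of the threshold, 170 kept the direction but no longer passed, 53 passed only under the alternative, 30 reversed and 3 list medians of single libraries, for monocytes in CTR and oligodendrocytes in PBS, moved in size under another prior count with the same direction. None of the 21 called genes named by the rule reversed; the other called genes were not followed one by one. Where a value moved or reversed the cause was not tested. Depth limits the single-library comparisons, as a count of 0 allows up to 0.467 CPM in the shallowest library.

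The 10 genes of CD45.1 TAµ against CD45.1 µ became 23 with no filter, 2 with the stricter filter, 217 with DESeq2, 3 with the legacy fit, 2 with no block and 24 with all 11 libraries, and 0 to 24 with 1 library left out. The 4 genes of CD45.2 µ against CD45.1 µ became 277 with DESeq2, 0 with the stricter filter, limma-voom, the legacy fit, no block or the 6 libraries alone, and 0 to 29 with 1 library left out. The 0 genes of ICV against IV became 8 with no filter, 147 with DESeq2, 1 with the 6 libraries alone and 6 with all 11, and 0 to 28 with 1 left out. The 29 genes of ITL against IV became 12 with the stricter filter, 150 with DESeq2, 66 with limma-voom, 10 with the legacy fit, 13 with no block and 49 without IV CD45.2 µ and ICV CD45.1 µ, and 0 to 35 with 1 left out. Thinning gave 30 genes, of which 28 were shared. The 0 genes of ITL against ICV became 2 with no filter, 30 with DESeq2, 1 with the 6 libraries alone, 2 with all 11 and 2 without IV CD45.2 µ and ICV CD45.1 µ, and 0 to 3 with 1 left out.

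The 6, 9, 6, 8 and 6 lists called by camera in these 5 contrasts became 0 in each with an estimated correlation and 0 in each with fry's one-way test. Without IV CD45.2 µ and ICV CD45.1 µ the list count was 3 for CD45.1 TAµ against CD45.1 µ, 14 for ICV against IV and 15 for ITL against IV. For ICV against IV only CD45.1 TAµ kept both routes in that fit.

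The reversals were in 4 genes that did not pass. Without IV CD45.2 µ and ICV CD45.1 µ, Trem2 (-0.32) and Apoe (-0.32) turned for CD45.1 TAµ against CD45.1 µ, Ptprc (0.39) for CD45.2 µ against CD45.1 µ, Ptprc (-0.16) for ICV against IV, and Trem2 (-0.22) and Cx3cr1 (-0.12) for ITL against ICV. With limma-voom Ptprc turned for CD45.2 µ against CD45.1 µ (0.16) and Cx3cr1 for ITL against ICV (-0.055). With 1 library left out, log2 fold changes for CD45.1 TAµ against CD45.1 µ ran from -0.23 to 0.67 for Trem2, -0.17 to 0.13 for Cx3cr1 and -0.31 to 0.57 for Apoe. For CD45.2 µ against CD45.1 µ they ran from -0.23 to 0.15 for Ptprc and -0.50 to 0.38 for Trem2, and for ICV against IV from -0.41 to 0.46 for Trem2. For ITL against IV they ran from -0.13 to 0.74 for Trem2 and -0.24 to 0.61 for Apoe. For ITL against ICV they ran from -0.10 to 0.24 for Ptprc, -0.18 to 0.68 for Trem2, -0.12 to 0.17 for Cx3cr1 and -1.29 to 0.028 for Apoe.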

Other observations

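In this part the test of linkage to Ptprc and the splits of the libraries were set before their results were seen, and the tests of cell mixture, depth, neutrophils, handling, graft-derived state and male cells were chosen after the result was seen.

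The granule genes Mpo and Elane were read per library. Mpo had 33.7 CPM in IV CD45.1 TAµ, 106 CPM in ICV CD45.1 TAµ and 2.91 CPM in ITL CD45.1 TAµ, against 3.15 CPM in IV CD45.1 µ and 0 counts in the other CD45.1 µ libraries. Elane had 12.1, 31.2 and 0.896 CPM in these CD45.1 TAµ libraries and 0.0583 CPM, 0 counts and 1.39 CPM in CD45.1 µ by IV, ICV and ITL, so it was not higher by ITL. Neither passed the test, and of the stem and progenitor list 9 members were fitted higher and 8 lower in CD45.1 TAµ (median 0.13, camera adjusted p = 0.557); 0 changed over all genes, and 2 rose and 1 fell when adjusted over the list alone. The library closest to PBS was IV CD45.1 TAµ, with a Spearman correlation across genes of 0.982, and genes are not independent replicates. The monocyte gene Ccr2 had 125, 32.9 and 99.5 CPM in CD45.1 TAµ by IV, ICV and ITL and 28.3, 39.1 and 26.6 CPM in CD45.1 µ.

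Other lists passed camera in 0 of the 5 contrasts. Their lowest adjusted p was 0.371 for disease-associated microglia, 0.407 for lysosome and phagocytosis, 0.173 for lipid and cholesterol handling, 0.294 for oxidative phosphorylation, 0.326 for glycolysis and hypoxia, and 0.0843 for TGF-beta signalling. It was 0.208 for dendritic cells, 0.168 for B cells and 0.194 for neurons. Y-linked transcripts summed to 348, 74.4 and 162 CPM in CD45.1 µ by IV, ICV and ITL, 458, 210 and 314 CPM in CD45.1 TAµ, and 42.2, 1.33 and 3.43 CPM in CD45.2 µ. They summed to 0.0504 CPM in PBS and 339 CPM in CTR.

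Sall1 and Xist were lower in CD45.1 TAµ than in CD45.1 µ. Unequal depth is argued against: with every library thinned to 6090589 counts, 7 of the 7 genes that fell still passed, with Sall1 at -4.90. A candidate explanation is that CD45.1 µ libraries held cells of the CD45.2 µ type, which the sort by allele should remove. The share implied by Xist was inside the range of the shares implied by the 6 other fallen genes in 1 of 3 routes (IV 7.64% against 12% to 80.6%, ICV 80.5% against 55.7% to 145%, ITL 24.7% against 25.2% to 67.5%). This cannot decide on mixing, since it assumes that CD45.2 µ shows the profile of the added cells. The 6 genes also came from the same contrast. By ICV their median share was 110%, above the CD45.2 µ level itself, which no mixture of these profiles can give. Xist and Y-linked transcripts stood together in each CD45.1 µ library: 294 and 348 CPM by IV, 5702 and 74.4 by ICV, 1304 and 162 by ITL. These libraries thus held transcripts of both female and male cells. Whether the female cells were of the CD45.2 µ type stays open. Ctse, low in CD45.2 µ, stood in CD45.1 µ at 107%, 28.3% and 111% of its CD45.1 TAµ level by IV, ICV and ITL. The median of Y-linked genes stood at 64.7%, 37.1% and 52.2%. Ctse was thus lower in CD45.1 µ only by ICV, while the Y-linked median was lower by every route. A difference between the cell populations themselves stays open and was not tested.

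Immediate-early genes were lower as a list in ITL than IV. Depth is argued against, as 28 of the 29 called genes still passed after thinning. Fewer neutrophils in ITL stay open: in the CD45.2 µ pair, where the neutrophil list was higher in ITL by 7.59, the immediate-early list was still lower by a mean log2 difference of -0.335, but this is a single pair and short of the bound of -0.5 set for it. Handling of the cells during isolation could also lower these genes, and the list was lower in 3 of 3 pairs, but handling and route cannot be told apart because the labels give no isolation day. An effect of the route on the cells was not tested apart from handling. Nor can route be parted from the sex of the cells, as Xist was higher and Y-linked transcripts were lower in ITL in each population.

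Ctse was higher in CD45.1 than in CD45.2 libraries. A graft-derived state alone is argued against: Ctse was at least 7.41 times as high in each CD45.1 TAµ library (194 CPM or more) as in the PBS and ICV CD45.2 µ libraries, whose graft-derived list means (7.80 and 7.75 log2 CPM) were like those of CD45.1 TAµ (7.65 to 8.14). Male cells might carry more Ctse, and the lowest CD45.1 TAµ library had 75.2 times the level of CTR, which expressed Y-linked genes, but 1 library of another state cannot settle this. Ctse and Ptprc lie on chromosome 1, and 24 of 199 tested neighbours of Ptprc (12.1%) had an unadjusted p under 0.05 against 1091 of 12509 other genes (8.72%; one-sided Fisher's exact test, p = 0.0683), which leaves a linked strain variant open. A difference between donor and host cells was not tested.

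Each contrast of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real split is among the splits counted below as giving as many genes. For CD45.1 TAµ against CD45.1 µ the real split gave 10 genes, the highest other split 2, and 1 split gave as many. For CD45.2 µ against CD45.1 µ the real split gave 4, the highest other 198, and 2 splits gave as many. That other split set IV CD45.1 µ, ICV CD45.1 µ and ICV CD45.2 µ against the other 3 libraries, so that both ICV libraries stood on one side and both ITL libraries on the other. The splits were not kept within routes, although route stayed in the model. Why that count was so far above the real one, and what those genes reflect, was not tested. For ITL against IV the real split gave 29, the highest other 3, and 1 split gave as many. For ICV against IV the real split gave 0 and the highest other 5, and for ITL against ICV both were 0. In each 10 of 10 splits gave as many, which a real count of 0 fixes in advance. The unadjusted counts and those of DESeq2 were 1230 and 147 for ICV against IV, and 506 and 30 for ITL against ICV.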
